A study of Bos taurus with 14 samples.

How the data were processed

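Liver was taken after slaughter on day 90 from 14 Holstein bull calves, 7 of a control group (CON) and 7 given a postbiotic (DCLI), and 1 poly(A)-selected RNA library per calf was sequenced on a DNBSEQ instrument, per the labels. The libraries titled as treated were taken as the DCLI group, the only treated group that the design names. The submitters' processing notes name SOAPnuke 1.5.6, RSEM 1.3.1 and DESeq2 1.4.5. Reads were dropped if over 5% of their bases were unknown or over 20% had a quality score under 15, per the labels' protocols. The aligner and the genome build are not given in the sources used here.

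The authors deposited 1 table of TPM, a unit scaled for transcript length and library total, for 49721 RefSeq transcripts of 17469 genes, written to 2 decimals. TPM has the same total in each library (the columns summed to between 999997.1 and 1000000.3), so the sequencing depth of a library is unknown, and no counting interval or detection limit can be given. A transcript that takes a large share of the total lowers every other TPM value of that library. No mitochondrially encoded gene was found in the table. Of the gene IDs, 98.8% carried a symbol in the RefSeq gene table of assembly ARS-UCD2.0, which was used for names only, and 8 symbols that a spreadsheet had turned into dates were restored through it.

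TPM was summed over the transcripts of each gene. Genes with at least 1 TPM in at least 7 of the 14 libraries were kept, which left 11905 genes. Values were tested as log2(TPM + 1), so fold changes are on that scale and understate the change of genes of low level. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. The design held no covariate, because the labels name no batch. Every value is the level in 1 calf, and n counts calves.

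Before the data were examined, 38 gene lists were fixed (liver pathways and markers of cell types that a piece of liver could hold), with 972 entries, of which 917 matched a gene. The 35 lists with at least 5 measured genes were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the lists. The same test with a correlation estimated for each list, and fry, were set beside it. For each list the members past an adjusted p of 0.05 were counted over all genes and adjusted over the list alone. List means per calf were compared by an exact permutation test over all 3432 assignments of the calves. The share of the squared distance between libraries that lay between the groups (PERMANOVA) and the difference in the mean distance to the group centroid were tested over the same assignments.

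The genes named were also set by a rule fixed before the data were examined. They are the 10 genes per direction with the largest change among those past the threshold, filled up by lowest unadjusted p where fewer than 5 passed, leaving out genes without a symbol. To these come up to 4 genes of lowest unadjusted p in each list described, any other list member past the threshold adjusted over the list alone, and the 5 genes of highest mean TPM. Genes named outside this rule are said to be so, and some genes that the rule takes are not reported here.

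The limma step was tested on simulated data with the 11905 genes of this comparison, noise drawn independently for each gene and 50 genes changed per fold size. It recovered 42% of genes changed 1.5-fold, 90% of those changed 2-fold, 96% of those changed 3-fold and 96% of those changed 4-fold, with 12 unchanged genes called. With the residuals of the real libraries as noise, which keeps what genes share, it recovered 56%, 84%, 96% and 98% in the same order. False calls say nothing in that run, since such residuals hold no difference between the groups by construction. For the same reason each estimated change equals the one put in. Recovery in that run therefore reflects only the variance of each gene, without sampling error of the difference, and is no estimate of power. In both runs many genes changed strongly at once, which eases the adjusted threshold, so these rates overstate recovery where few genes change. They do not show that a 2-fold change would have been called in the real comparison.

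Alternatives tried were pseudocounts of 0.1 and 5, no filter and a mean of at least 5 TPM, median-ratio scaling, quantile normalization, rescaling without the 20 most abundant genes, the replicate number as a block, other variance models, sample weights, an exact rank-sum test, other thresholds and distances, and leaving out each calf in turn. Chosen after the data were seen were leaving out control calf 2 together with DCLI calf 6, the level of haptoglobin mRNA as a covariate, and transcripts in place of genes. Correlations across calves used 100000 resamples. GC content and transcript length were not tested, because no sequences were used here. Figures were drawn with matplotlib 3.10.9.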

Results

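The data are the liver transcriptomes of 14 Holstein bull calves at the end of weaning. Control calves (CON, n = 7) and supplemented calves (DCLI, n = 7) were reared alike on milk replacer at 1.75% of body weight. Starter was offered from day 33, milk replacer was cut to 50% on day 82 and weaning was complete by day 89. DCLI calves also received 1 g per day of dead cells of Lactobacillus ingluviei strain CR37, a postbiotic, which is a preparation of inactivated microbes. The samples were taken on day 90. The comparison asks how the supplement bears on gene expression in the liver. Between 15274 and 15781 genes had a value above 0 in a library, and 11430 to 12358 reached 1 TPM. The 20 most abundant genes held 26.4% of the TPM in CON (SD 2.77, n = 7) and 27.3% in DCLI (SD 4.0, n = 7). Levels were highest for ALB, which encodes serum albumin, at 48228 TPM in CON (SD 10840) and 55193 TPM in DCLI (SD 19680, n = 7 each). ORM1, APOA2, FGG and MT1A followed. They encode an acute phase glycoprotein, an apolipoprotein, a fibrinogen chain and a metallothionein.

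No gene passed the adjusted threshold, and the 10 genes of lowest unadjusted p among those higher in DCLI calves had the values that follow. SDHA, the flavoprotein of succinate dehydrogenase, had 170 TPM in CON (SD 35.9) and 244 TPM in DCLI (SD 22.0), a log2 fold change of 0.54 ± 0.12 (SE, n = 7 each). DLST, a subunit of the oxoglutarate dehydrogenase complex of the citric acid cycle, had 25.5 and 39.8 TPM (log2 fold change 0.65 ± 0.14). ILVBL, an enzyme of fatty acid alpha-oxidation, had 24.5 and 41.1 TPM (0.78 ± 0.16), and NUBPL, an assembly factor of respiratory complex I, had 3.42 and 5.96 TPM (0.65 ± 0.15). CD320, the cell surface receptor for transcobalamin, and RPIA, an enzyme of the pentose phosphate pathway, stood 0.46 ± 0.10 and 0.50 ± 0.12 higher. The largest difference of the group was in FBXO32, which encodes the F-box ubiquitin ligase atrogin-1 and is induced in fasting muscle, with 3.65 TPM in CON (SD 2.11) and 11.98 TPM in DCLI (SD 5.01), a log2 fold change of 1.56 ± 0.37. CCL16, a chemokine made by liver, KIF1C, a kinesin motor, and NCLN, an endoplasmic reticulum membrane protein, completed the 10 genes, with log2 fold changes of 0.59, 0.45 and 0.52. Each of the 10 lay above the control median in 7 of 7 DCLI calves. The genes were chosen by low p in this same comparison, so that count follows largely from the choice and is no separate evidence. Over the alternatives tried, the log2 fold change ran from 0.95 to 1.98 for FBXO32, from 0.38 to 0.78 for NUBPL and from 0.32 to 0.58 for RPIA.

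The 10 genes of lowest unadjusted p among those lower in DCLI calves also missed the adjusted threshold. LGALS3, which encodes galectin-3, had 15.98 TPM in CON (SD 10.6) and 5.53 TPM in DCLI (SD 1.51), a log2 fold change of -1.19 ± 0.31 (SE, n = 7 each). TREM2, a lipid-binding receptor of macrophages, had 2.93 and 1.02 TPM (-0.86 ± 0.23). IL18BP, the secreted inhibitor of interleukin 18, had 6.13 and 2.38 TPM (-1.01 ± 0.25), and PLD4, a lysosomal exonuclease of myeloid cells, had 9.46 and 4.71 TPM (-0.94 ± 0.25). RPL23A, a protein of the large ribosomal subunit, had 1469 TPM in CON (SD 188.5) and 1089 TPM in DCLI (SD 76.1), a log2 fold change of -0.42 ± 0.11. ADIRF, DBNDD2, ZSCAN26, TSNAX and CETN3 completed the 10 genes, with log2 fold changes of -0.94, -0.59, -0.49, -0.33 and -0.30. Of the 10, 7 lay below the control median in every DCLI calf. PLD4, ADIRF and DBNDD2 lay below it in 6 of 7. These counts too follow largely from the choice of the genes by low p. Over the alternatives tried, the log2 fold change ran from -1.30 to -0.37 for TREM2 and from -1.27 to -0.55 for IL18BP. It ran from -1.36 to -0.86 for LGALS3, from -1.13 to -0.59 for PLD4 and from -0.60 to -0.27 for ZSCAN26. Control calf 2 had the highest LGALS3, IL18BP, PLD4 and DBNDD2 of all calves. Without it their log2 fold changes were -0.98, -0.86, -0.82 and -0.48. Control calf 3 had 6.67 TPM of TREM2, and the control mean of TREM2 was 2.31 TPM without that calf.

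**Figure D1:**
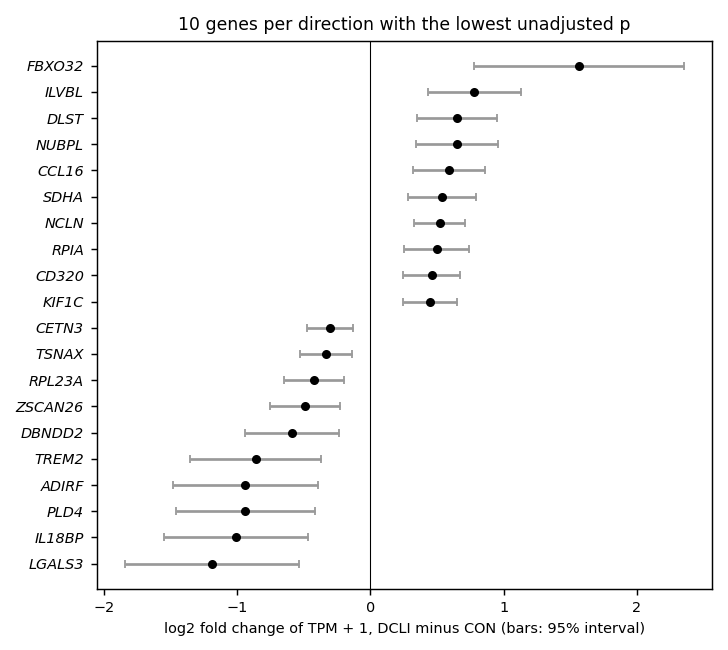
Log2 fold change of TPM + 1 (DCLI minus CON, x axis) for the 10 genes per direction with the lowest unadjusted p, with bars for the 95% interval from limma (n = 7 calves per group). FBXO32 lies at 1.56 and LGALS3 at -1.19, and no gene passed the adjusted threshold.

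By limma, 0 of 11905 genes passed an adjusted p of 0.05, and the lowest adjusted p was 0.352, that of NCLN. At an unadjusted p under 0.05 there were 1058 genes, 678 higher and 380 lower in DCLI, where chance alone gives 595, and 36 of them differed at least 2-fold. An exact rank-sum test also left 0 genes after adjustment and 821 before it. The 95% interval of a fold change reached a median of 0.29 to either side on the log2 scale. Without control calf 7, whose library was the control closest to a DCLI library (r = 0.988 with DCLI calf 7), the count was 12 genes. Among them were SDHA, DLST, ILVBL and NCLN. With the replicate number as a block the count was 1 gene, FBXO32 (adjusted p 0.00687 by limma), and with sample weights it was 1388.

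Genes of fatty acid oxidation and ketogenesis stood higher in DCLI calves as a group. Of 29 measured members 27 were higher, with a median log2 fold change of 0.34 and an adjusted p of 2.75e-08 by camera with the preset correlation. With an estimated correlation the list was not called (adjusted p = 0.619). CPT1A, which admits long-chain fatty acids into mitochondria, had 97.6 TPM in CON (SD 25.3) and 135 TPM in DCLI (SD 18.7, n = 7 each). HADHA, the alpha subunit of the mitochondrial trifunctional protein, had 119 and 194 TPM. CRAT, carnitine acetyltransferase, stood 0.64 higher on the log2 scale. These 3 genes, chosen by low p in this comparison, lay above the control median in 7 of 7 DCLI calves. Of the list, 0 members passed the threshold over all genes or adjusted over the list alone. The exact permutation p of the list mean per calf was 0.0612 (mean -0.20 in CON, SD 0.36, and 0.20 in DCLI, SD 0.34, n = 7 each). This was the lowest of the 35 lists tested, and 0 of them had an exact permutation p under 0.05.

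Other metabolic lists lay on the same side. In gluconeogenesis, glycolysis and glycogen metabolism 20 of 25 members were higher (median log2 fold change 0.19, preset adjusted p 0.000786, adjusted p = 0.619 with an estimated correlation). PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, had 155 and 229.9 TPM, LDHA, a lactate dehydrogenase subunit, 166 and 296 TPM, and PYGL, liver glycogen phosphorylase, 221 and 284 TPM. In the urea cycle and amino acid catabolism 21 of 27 members were higher (median 0.14, adjusted p = 0.619 with an estimated correlation). CPS1, the entry enzyme of the urea cycle, stood 0.44 higher and the transaminase gene GOT1 0.85 higher. Among genes of propionate and cobalamin metabolism 10 of 16 were higher (median 0.11, adjusted p = 0.619 with an estimated correlation), with MUT, the methylmalonyl-CoA mutase, at 192 and 249 TPM and TCN2, transcobalamin, at 219 and 268 TPM. Cytochrome P450 and other phase I enzymes (26 of 34 higher, median 0.22) and bile acid synthesis and transport (17 of 22, median 0.17) were higher too, with adjusted p of 0.625 and 0.619 with an estimated correlation. NR1I2, the pregnane X receptor, stood 0.57 ± 0.17 higher, and ABCB4, the phospholipid exporter of bile, 0.47 ± 0.15 (SE). Heat shock genes were higher in 17 of 19 cases (median 0.15, adjusted p = 0.619 with an estimated correlation), HSPD1, the mitochondrial chaperonin, by 0.43 (0.28 without control calf 2). The preset adjusted p of these 5 lists lay between 0.00105 and 0.0422. Without control calf 2 the calls of the urea cycle, propionate, P450 and bile acid lists were lost, with adjusted p of 0.218, 0.182, 0.200 and 0.208. Their medians were then 0.12, 0.13, 0.15 and 0.13, against 0.14, 0.11, 0.22 and 0.17 with that calf. Other single calves ended these calls too: DCLI calves 1 and 4 for all 4 lists, DCLI calf 3 for the propionate and bile acid lists, control calf 1 for the urea cycle and propionate lists, and control calves 4 and 7 and DCLI calf 5 for the propionate list (adjusted p no higher than without control calf 2). Quantile normalization ended the calls of the bile acid, urea cycle and propionate lists (adjusted p of 0.108, 0.0741 and 0.156), a mean of at least 5 TPM those of the urea cycle and propionate lists (0.0518 and 0.0570), median-ratio scaling that of the propionate list (0.0727) and sample weights those of the urea cycle and propionate lists (0.655 and 0.293). With 1 calf left out the medians ran from 0.08 to 0.22 for the urea cycle, from 0.06 to 0.17 for propionate, from 0.15 to 0.35 for P450 and from 0.11 to 0.25 for heat shock genes, the first 2 lowest without DCLI calf 4, the first 3 highest without DCLI calf 6 and the last highest without DCLI calf 4. With sample weights the median of heat shock genes was 0.31.

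Nuclear-encoded genes of oxidative phosphorylation were divided. Of 44 members 28 were higher and 16 lower, with a median log2 fold change of 0.07 (preset adjusted p 0.00195, adjusted p = 0.619 with an estimated correlation). The call was also lost with quantile normalization and with sample weights (adjusted p of 0.0654 and 0.0643), and the median was 0.03 with quantile normalization, 0.13 without DCLI calf 1 and 0.05 without DCLI calf 3. It was the one list with members past the threshold adjusted over the list alone, 9 higher and 1 lower, against 0 over all genes. Among the 9 were SDHA, CYC1, NDUFS1, NDUFV1, ATP5F1A, ATP5F1B, UQCRC1 and UQCRC2, which encode catalytic, electron-carrying or core subunits of complexes I, II, III and V. The log2 fold changes of these genes ran from 0.29 for UQCRC2 to 0.54 for SDHA. The member that fell, adjusted over the list alone, was NDUFB1, an accessory subunit of complex I, with 182 TPM in CON (SD 37.2) and 125 TPM in DCLI (SD 39.6), a log2 fold change of -0.60. Of 14 NDUFA and NDUFB genes of complex I, 5 were higher and 9 lower (median -0.02). Of 6 NDUFS and NDUFV genes, 5 were higher and 1 lower (median 0.24). By fry, the test for change in either direction gave an adjusted p of 0.0211 for this list, the one list it called, and the test for change in one direction gave 0.550. Genes of ribosomal proteins were lower in 56 of 63 cases (median -0.15, preset adjusted p 7.11e-07, adjusted p = 0.619 with an estimated correlation). RPL22 had 739 and 556 TPM and RPL19 1663 and 1364 TPM. Both, chosen by low p in this comparison, lay below the control median in 7 of 7 DCLI calves. Without control calf 5 the median of the ribosomal list was -0.09. It was -0.09 with quantile normalization and -0.08 with sample weights. Genes of ribosomal proteins have short mRNAs. The effect of transcript length was not tested, for them or for the genes of oxidative phosphorylation.

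Genes of 4 immune lists leaned lower in DCLI calves, and in these lists 1 control library stood apart. Antigen presentation genes were lower in 22 of 25 cases (median -0.44, preset adjusted p 7.14e-06, adjusted p = 0.619 with an estimated correlation). JSP.1, a classical major histocompatibility class I gene, had 655 TPM in CON (SD 420.0) and 267 TPM in DCLI (SD 99.8, n = 7 each), and BOLA-DRB3, a class II gene, had 347 and 201 TPM. Such genes are polymorphic and have near copies, so their levels are uncertain. Markers of T and NK cells were lower in 17 of 17 cases (median -0.46), and those of Kupffer cells and macrophages in 14 of 15 (median -0.38), with CD3G at 12.9 and 5.55 TPM and TIMD4, a receptor of resident macrophages, at 67.8 and 40.6 TPM. The adjusted p of both lists was 0.619 with an estimated correlation. In Toll-like receptor and NF-kB signalling 25 of 32 members were lower (median -0.24, adjusted p = 0.619 with an estimated correlation), among them the chemokine genes CCL4 (-1.06 ± 0.32) and CCL5 (-1.19 ± 0.44, SE). In these 4 lists 0 members passed the threshold adjusted over the list alone. The exact permutation p of their list means per calf lay between 0.148 and 0.2885. In control calf 2 the T and NK cell markers stood 2.05 above the mean of all calves on the log2 scale and the macrophage markers 1.53. Without that calf the medians of the antigen presentation, T and NK cell, macrophage and Toll-like lists were -0.21, -0.16, -0.19 and -0.08 (the macrophage median was -0.24 without DCLI calf 1), and the control means of CD3G and CCL5 were 7.53 and 54.8 TPM, against 12.9 and 89.0 TPM with it. Other settings made these medians smaller too, with the calls kept. That of the Toll-like list was -0.13 with log2(TPM + 5), -0.11 with no filter, -0.11 with a mean of at least 5 TPM and -0.11 with sample weights, and with sample weights those of the antigen presentation, T and NK cell and macrophage lists were -0.25, -0.27 and -0.15.

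The remaining lists called lower by the preset correlation were cholesterol synthesis (20 of 23 members lower, median -0.19), cell cycle (26 of 29, median -0.26), immediate early genes (18 of 21, median -0.18), stellate cell and matrix markers (16 of 20, median -0.10), neutrophil markers (6 of 6, median -0.36) and cholangiocyte markers (6 of 8, median -0.33). Their preset adjusted p lay between 0.00728 and 0.0278, and with an estimated correlation the adjusted p was 0.732 for cell cycle, 0.715 for cholesterol synthesis and 0.619 for the others. FDPS and FDFT1, enzymes of the sterol pathway, stood at 64.8 and 33.9 TPM and at 68.6 and 45.2 TPM. FOS, a subunit of the transcription factor AP-1, had 5.83 and 3.01 TPM. RRM2, a subunit of ribonucleotide reductase, had 4.77 and 3.09 TPM, and its control mean was 3.42 TPM without control calf 2. Among cholangiocyte markers SPP1, osteopontin, had 7.95 and 3.45 TPM, and CLDN4, a tight junction protein, 25.9 and 11.4 TPM. ACTA2, smooth muscle actin, had 64.9 and 46.8 TPM, and LTF, lactoferrin, 10.4 and 6.06 TPM, the latter 2.08 TPM without DCLI calf 6. Leaving out 1 calf ended each of these 6 calls: control calf 5 or 6 or DCLI calf 2 for cholesterol synthesis, stellate and cholangiocyte markers, DCLI calf 6 for cholesterol synthesis, DCLI calf 3 for stellate, cholangiocyte and immediate early genes, DCLI calf 4 for stellate markers, control calf 2 or DCLI calves 4 or 6 for cell cycle, and control calves 4 or 5 or DCLI calves 2, 3, 5 or 7 for neutrophil markers. The highest adjusted p with a calf left out lay between 0.0631 and 0.351. Without control calf 2 the medians of the cell cycle and immediate early lists were -0.07 and -0.07. With 1 calf left out the median ran from -0.31 to -0.08 for cholesterol synthesis (without control calf 4 and DCLI calf 6, with -0.31 without DCLI calf 3 and -0.10 without control calf 6), from -0.62 to -0.24 for neutrophil markers (without DCLI calves 6 and 5) and from -0.19 to -0.05 for stellate markers (without control calves 7 and 1, with -0.16 without control calf 4), and it was -0.12 for cell cycle without DCLI calf 6 and -0.16 without DCLI calf 1. Other settings ended the calls of cholangiocyte markers (no filter, a mean of at least 5 TPM, median-ratio scaling, quantile normalization and rescaling, adjusted p from 0.0630 to 0.276, with a median of -0.04 under the first 2), neutrophil markers (a mean of at least 5 TPM, median-ratio scaling and quantile normalization, 0.0567 to 0.0643), stellate markers (median-ratio scaling, 0.0673) and cell cycle (a mean of at least 5 TPM, 0.0752, and sample weights, 0.734). Where the calls stayed, the medians were -0.13, -0.10 and -0.15 with log2(TPM + 5) for cell cycle, immediate early genes and cholangiocyte markers, -0.19 with no filter for neutrophil markers, and -0.07, -1.22 and -0.06 with sample weights for cholesterol synthesis, neutrophil and stellate markers. In all, camera with the preset correlation called 19 of 35 lists, 8 higher and 11 lower, and with an estimated correlation, as by fry in one direction, it was 0. Control calf 2 and DCLI calf 6 were also left out together, a choice made after the data were seen. Then 14 lists were called, 6 higher and 8 lower. The calls of T and NK cells, macrophages, cell cycle, the urea cycle and propionate metabolism were lost (adjusted p of 0.0635, 0.0819, 0.928, 0.128 and 0.0546). The medians of these lost lists were -0.10, -0.06, 0.06, 0.20 and 0.18, so that of cell cycle changed sign. Among lists still called, medians were -0.12 for antigen presentation, -0.04 for Toll-like signalling, -0.04 for immediate early genes and -0.71 for neutrophil markers.

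**Figure D2:**
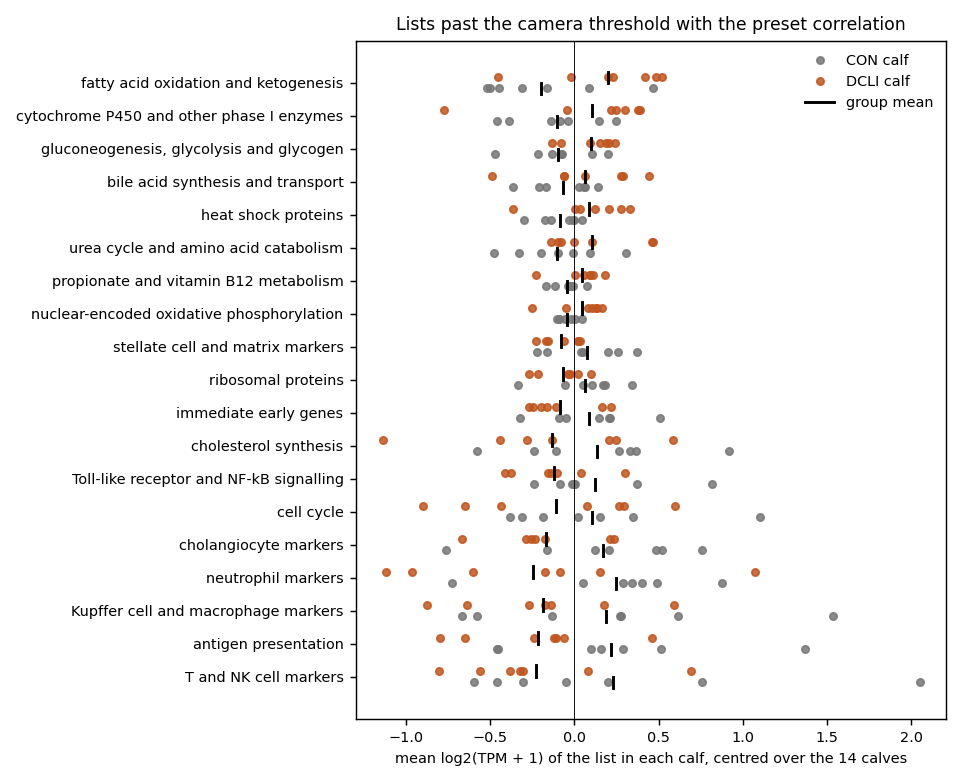
Mean log2(TPM + 1) of each list called with the preset correlation (x axis, centred over the 14 calves), 1 point per calf, grey for CON and orange for DCLI, with a black bar for each group mean. The groups overlap in each list, and control calf 2 lies at 2.05 for T and NK cell markers.

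Hepatocyte markers were not called (9 of 13 higher, median 0.12, preset adjusted p 0.391), nor were acute phase proteins (15 of 27 higher, median 0.04, preset adjusted p 0.563) or interferon-stimulated genes (24 of 39 lower, median -0.10, preset adjusted p 0.158). HAMP, which encodes hepcidin, the hormone that limits iron release, had 272 TPM in CON (SD 140.2) and 663 TPM in DCLI (SD 515, n = 7 each). IL6R, the interleukin 6 receptor, had a log2 fold change of 0.59 ± 0.20 and ORM1 one of -0.73 ± 0.41 (SE; -1.11 without DCLI calf 6), and all 3 missed the adjusted threshold. The interferon-induced chemokine genes CXCL9 and CXCL10 had 84.97 and 12.6 TPM and 50.7 and 18.7 TPM. Control calf 2 alone had 385 TPM of CXCL9 and 145 TPM of CXCL10, and the control means without it were 34.99 and 34.9 TPM. HP, haptoglobin, chosen after its values were seen, ran from 46.6 to 21480 TPM in CON and from 138 to 29341 TPM in DCLI, and its group difference had an exact permutation p of 0.862 (two-sided).

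**Figure D3:**
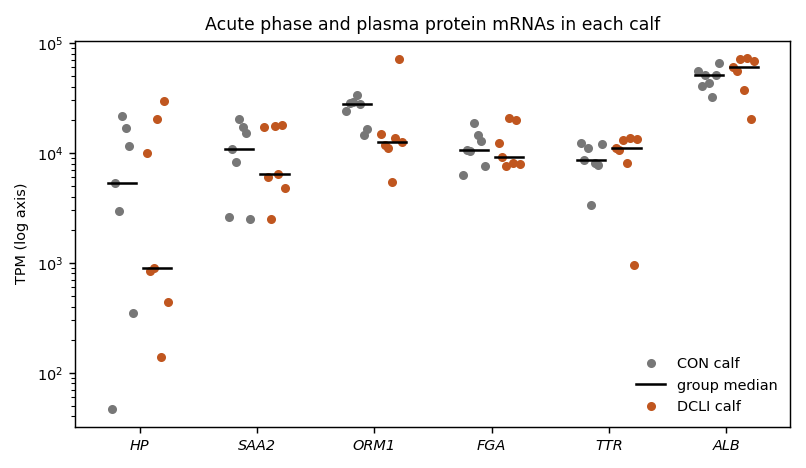
TPM (y axis, log scale) of mRNAs of acute phase and other plasma proteins, 1 point per calf, grey for CON and orange for DCLI, with a black bar for each group median. HP spans 46.6 to 29341 TPM over the 14 calves, and DCLI calf 6 has the highest ORM1 (71549 TPM) and the lowest TTR (961 TPM).

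In the fit planned as the main one, the whole transcriptome did not separate the groups beyond the spread between calves. In 3 of the alternatives the exact permutation p fell just under 0.05, without adjustment over the alternatives. In the others it stayed above 0.05. Group membership held 10.9% of the squared distance between libraries, where the median assignment of calves held 6.98% (exact permutation p 0.134 over 3432 assignments). The first principal component took 28.9% of the variance and the second 20.5%, with exact permutation p between the groups of 0.324 and 0.0612. The mean distance of calves to their group centroid was 38.2 in CON and 34.9 in DCLI (exact permutation p 0.522). The share between the groups was 14.7% without control calf 7 (exact permutation p 0.0443), 12.1% with quantile normalization (0.0472) and 12.3% with Spearman distance (0.0443). Control calf 7 had the control library closest to a DCLI library (r = 0.988 with DCLI calf 7), so leaving it out favours separation. With any other calf left out, the exact permutation p lay between 0.0857 and 0.244. Without control calf 2 the difference in spread turned to 0.449 from -3.24.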

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

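The tests of haptoglobin, of control calf 2 and of shared variation within lists were chosen after those results were seen; the splits of the calves were planned beforehand. Each value reported was compared within its group of 7 calves on the log2 scale used for testing, although levels below are printed in TPM. A calf was picked out where its gap to the nearest other, relative to the group's range on that scale, exceeded Dixon's 95% critical value. Gaps in TPM were not tested and could pick out other calves. Of 308 groups of values 26 met the rule on the log2 scale, where chance alone gives about 15 if values are normally distributed. DCLI calf 6 had 9 of them and control calf 2 had 6.

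DCLI calf 6 had the highest ORM1 of its group, 71549 TPM against 14705 in the next calf, and the highest LTF, 29.9 against 4.07 TPM. It had the lowest APOA2 (11826 TPM), TF (4665 TPM), AKR1D1 (69.8 TPM) and PCK2 (154 TPM). Its list means were the lowest of its group for hepatocyte markers (-0.55, log2 relative to all calves), for fatty acid and triglyceride synthesis (-0.60) and for phase I enzymes (-0.77). Other single values lay far from their group. DCLI calf 4 had the lowest CPT1A (95.3 TPM) and the highest CPS1 (1207 TPM). DCLI calf 1 had the lowest TSNAX (7.53 TPM), TIRAP (5.81 TPM), CYC1 (73.4 TPM), UQCRC1 (103 TPM) and KRT19 (1.14 TPM), and DCLI calf 2 the highest JUN (20.01 TPM) and NR4A1 (1.55 TPM). Among controls, calf 7 had the lowest RPL23A (1094 TPM) and calf 5 the lowest UQCRC2 (75.1 TPM).

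Control calf 2 had the highest PSMB8 (278 TPM), PSMB9 (136 TPM), CD3G (45.05 TPM), CD2 (20.2 TPM) and RRM2 (12.9 TPM) of the controls and the lowest HSPD1 (119.5 TPM). Its T and NK cell markers stood 2.21 above the mean of the other 13 libraries on the log2 scale, with 17 of 17 genes above. A lower share of hepatocytes, which raises all other cell types alike, is argued against by its cholangiocyte and stellate markers, which stood at -0.066 on average. Its hepatocyte markers stood at -0.34 (1 of 13 genes above the others) and its sinusoidal endothelial markers at 0.59 (13 of 13 above), so a lower share may add a part but cannot alone account for types that move apart. Blood left in the piece is argued against as the only source by erythroid and neutrophil genes, which stood 0.563 above the others when pooled. The 2 lists differed. Erythroid markers, with 4 genes, stood 0.758 above, past the highest of the other libraries (0.424). Neutrophil markers stood 0.433 above, within the others (highest 1.101). Blood may therefore add a part. More immune cells in that piece remain open. Macrophage markers were higher in 15 of 15 genes and B and plasma cell markers by 1.053, the smallest of the 3 immune lists, but in 7 of 9 genes, short of the 80% set for the test.

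Haptoglobin mRNA differed 630-fold between calves, 461-fold within CON and 212-fold within DCLI. Composition is argued against as the cause, since the ratio was 742 after the 20 most abundant genes were left out and the rest rescaled. HP ran opposite to the hepatocyte markers (Spearman rho -0.653). That list holds TF, which was lowest in DCLI calf 6, the calf of highest HP, so the sign alone does not measure the share of hepatocytes. The mean of the markers spanned only 0.81 log2 units over the calves, which argues against that share as the main cause of a 630-fold spread. The supplement explained 0.247% of the variance of log2 HP (exact permutation p 0.8625), which argues against it as the cause of this spread, though not against a small effect. What set the level of HP in a calf was not tested, because health records are not used here.

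The 19 lists called with the preset correlation can be set against chance. Of 100 splits of the 14 calves into 7 and 7, drawn from 1716 with the real one included, 28 called as many lists, and the highest of the others was 28 lists. Chance therefore cannot be excluded. The members of the called lists varied together from calf to calf, with a median estimated correlation of 0.39 against the preset 0.01, and with the estimated values 0 lists were called, which suggests that shared variation between calves could produce such calls. Control calf 2 carried much of the immune part: without it the mean difference of the 4 immune lists kept 44.7% of its size (-0.38 with it, -0.17 without), and the exact permutation p of the rest was 0.451. Transcript length and GC content stay open as explanations. Ribosomal protein genes, whose mRNAs are short, were lower in 56 of 63 cases. A length effect was not tested.

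For single genes, 22 of the 100 splits gave at least the 1058 genes at an unadjusted p under 0.05, and the highest of the others gave 2755. At an adjusted p of 0.05, where the real split gave 0, 4 of the other splits called genes, at most 62. Chance cannot be excluded for the real count. With sample weights estimated anew in each split, 5 of 100 splits called at least the 1388 genes of the real one, with 2434 as the highest of the others, so chance cannot be excluded there either.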

How the results depend on the processing

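Leaving out control calf 2 with DCLI calf 6, haptoglobin as a covariate and transcripts in place of genes were chosen after the data were seen. The count of 0 genes by limma stayed 0 in all settings but these: 1 gene, FBXO32, with the replicate block, 1388 with sample weights (1210 higher and 178 lower), 1058 at an unadjusted p and 36 of them at least 2-fold. Leaving out each calf gave 0 to 12 genes, the 12 without control calf 7. Sample weights gave DCLI calf 7 a weight of 5.93 and control calf 2 one of 0.336. The labels do not say whether the same replicate number in both groups pairs calves, and the values cannot settle it. Of 7 correlations of same-numbered calves 4 exceeded 0.1 (range -0.176 to 0.453), and 2 controls matched best with their own number. Lists called numbered 0 with an estimated correlation or by fry in one direction, and 1 by fry in either direction. In the settings that kept the preset correlation they numbered 13 to 21, 4 higher and 9 lower with quantile normalization. Of the 19 lists, 6 were called in all 27 of these fits: fatty acid oxidation, gluconeogenesis, heat shock, antigen presentation, Toll-like signalling and ribosomal proteins. With sample weights the tests of the urea cycle and cell cycle lists reversed (medians 0.10 and 0.16, the former against its test). The median log2 fold change of all genes was then 0.08, against -0.0052 in the main fit. Without adjustment over the settings, the separation passed its threshold with quantile normalization (12.1%, exact p 0.0472) and Spearman distance (12.3%, exact p 0.0443). It ran from 9.86% to 14.7% with 1 calf left out, past the threshold without control calf 7. The difference in spread ran from -6.50 to 0.449, the reversal without control calf 2. Of 3137 alternative fold changes of 117 named genes, 3063 kept direction and call, 67 came to pass the threshold and 7 reversed: ALB to -0.27 with quantile normalization, FGG to -0.31 with sample weights, and HP 5 times, to between 0.06 and 0.38 with 1 calf left out (full range -1.26 to 0.38). The cause of these changes was not tested. Depth is unknown from TPM, so no limit from depth can be given.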

Other observations

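The tests below on haptoglobin, clock genes and fatty acid oxidation were chosen after the data were seen; the test of the macrophage hypothesis was set before its result was. Across the 14 calves, the level of HP ran with a wider program. With the group in the limma fit, 545 genes followed HP past an adjusted p of 0.05, 82 higher with it and 463 lower. GPX3, a secreted glutathione peroxidase, LCN2, the siderophore-binding lipocalin, SERPINA3, a protease inhibitor, and SOCS3, an inhibitor of cytokine signalling, were among those higher, with slopes of 0.65, 0.25, 0.25 and 0.24 log2 units per log2 unit of HP. The 20 most abundant genes held 22.5% of TPM in control calf 1, of lowest HP, and 34.2% in DCLI calf 6, of highest HP. A lower TPM of other genes at higher HP may thus be partly composition, which was not tested for these relations. Of 35 lists, 6 were related to HP by both Pearson and Spearman correlation after adjustment over the lists, with 100000 resamples. The other acute phase genes ran with it (r = 0.971, rho = 0.952, permutation p 1e-05, the smallest the resamples can give, adjusted p 0.000175 and 0.00035). Neutrophil markers did so less closely (r = 0.736, rho = 0.754). Gluconeogenesis genes (r = -0.724, rho = -0.785), lipoprotein genes (r = -0.755, rho = -0.749) and fatty acid synthesis genes (r = -0.710, rho = -0.758) ran opposite. The permutation p of these 4 lists lay between 0.00125 and 0.00451 and their adjusted p between 0.0146 and 0.0226. Without the 2 calves farthest from the median of HP, r was 0.955 for acute phase genes, 0.856 for neutrophil markers, -0.741 for gluconeogenesis, -0.772 for lipoproteins and -0.645 for fatty acid synthesis. The widest gap between neighbouring calves in HP was 1.73 log2 units, between DCLI calf 3 (901 TPM) and control calf 3 (2982 TPM). Whether the calves form separate clusters was not tested.

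The closest opposite relation was with circadian clock genes (r = -0.925, permutation p 1e-05, adjusted p 0.000175; rho = -0.903, p 2e-05, adjusted p 0.00035). It was -0.944 within CON, -0.903 within DCLI and -0.906 without the 2 farthest calves. Of the 18 genes 16 were lower at higher HP, and 4 passed the threshold over all genes, among them PER2 (2.02 to 10.2 TPM over the calves), PER1 (18.5 to 53.9 TPM) and RORA (4.25 to 9.26 TPM). ARNTL and CLOCK, which encode the activators of the clock, had r of -0.147 and -0.161. The clock list did not differ between the groups (median 0.00, preset adjusted p 0.853). The hour of slaughter of each calf is not used here, and a part played by composition was not tested for this relation.

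Several lists not described in the report were not called. Lipoproteins (14 of 22 higher), coagulation (11 of 20), iron and haem (16 of 26), fatty acid and triglyceride synthesis (8 of 16), and growth hormone, IGF and insulin signalling (11 of 21) had medians of 0.10, 0.05, 0.07, 0.01 and 0.01. Complement (15 of 29 lower), phase II enzymes (17 of 30) and antioxidant defence (18 of 30) had medians of -0.08, -0.04 and -0.06, and the unfolded protein response was even (13 of 25 higher). Markers of B and plasma cells (8 of 9 lower), sinusoidal endothelium (8 of 13) and adipocytes (4 of 6) had medians of -0.14, -0.05 and -0.09. The preset adjusted p of these lists lay between 0.165 and 0.837. Erythroid markers, with 4 measured genes (median -0.32), and exocrine pancreas and gut markers, with 2, were too few to test, and mitochondrially encoded genes numbered 0.

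A hypothesis was that the higher level of fatty acid oxidation genes in DCLI calves came from a difference in acute phase state, since these genes ran opposite to HP (r = -0.628, rho = -0.618, permutation p 0.0186 and 0.0209, adjusted p 0.0723 and 0.0731). With log2 HP as a covariate the difference of the list mean was 0.37 against 0.39 without it, so that 94.2% was kept. Log2 HP differed by only -0.29 between the groups, so a high share was fixed in advance by that near equality. The slope on HP within the groups, times the difference of HP between them, accounts for 0.02 of the list difference (95% interval 0.01 to 0.04), and the mean of the other acute phase genes accounts for -0.01 (-0.02 to 0.00). Control calf 1 was the calf whose absence lowered the share kept most. Without it log2 HP differed by -1.26, 72.8% was kept, below the share that the test asked for, and the upper limit was 0.20 of 0.44. Acute phase state, as these genes measure it, was near equal between the groups. The test therefore says only that it accounts for little of the difference in these calves, and it may still be a small part. The difference itself had an exact permutation p of 0.0612 for the list mean.

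A second hypothesis was that LGALS3, TREM2 and SPP1, all lower in DCLI calves, mark fewer lipid-associated macrophages. SPP1 is also a cholangiocyte marker and stood in that list. Of 14 other measured genes of such macrophages 12 were lower in DCLI, and their mean differed by -0.30 (0.15 in CON, SD 0.39, and -0.15 in DCLI, SD 0.27, n = 7 each, exact permutation p 0.1206). The test leaves the hypothesis open, and without control calf 2 the difference was -0.18 (exact permutation p 0.245). The general list of Kupffer cell and macrophage markers was lower in 14 of 15 members, with a mean log2 fold change of -0.38. The test therefore cannot tell fewer lipid-associated macrophages from fewer macrophages of any kind.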
